A study of Homo sapiens with 14 samples.

How the data were processed

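ATAC-seq was carried out on LHCN myoblasts and RH30 rhabdomyosarcoma cells, with 100000 cells per library, a Tn5 reaction of 30 min and 12 PCR cycles, per the labels' protocols. The 14 libraries fall into 7 groups of 2: LHCN with vector or PAX3-FOXO1, RH30 with DMSO or QC6352, and RH30 with shCtrl, shKDM4B-813 or shKDM4B-814. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate cultures, so any p-value measures only the spread between these libraries, which may be technical.

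Per the submitters' processing notes the tools were BWA 0.7.12-r1039, Picard 1.65, SAMtools 1.3.1 and MACS2 2.1.1, with genome build hg19. Their settings, read filters and any shift of reads for the Tn5 cut are not given in the sources used here. The deposited files are narrowPeak lists, 1 per library, so peaks were called per library and replicates could be compared. Each list gives, from the authors' peak caller, a score per peak, which was not used here. The authors' fold value per peak is a ratio over background and was used only to describe and rank peaks within a list. The authors also deposited −log10 p and −log10 q per peak, and the latter ranked the peaks. Lists hold only peaks above a limit, with the lowest −log10 q at 2.00 to 2.60. Absence from a deposited list means that no peak passed that limit. Absence from a trimmed list, as used below, means only that none was among the strongest peaks kept.

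Read depth was not taken from the lists directly. Within a list every fold value was a whole multiple (tolerance 0.05 of a step, 100% of peaks) of a single step. The inverse of that step was read as the background pileup, together with any constant the caller adds before taking the ratio. It was 3.37 ± 0.016 with vector and 3.68 ± 0.27 with PAX3-FOXO1 in LHCN. In RH30 it was 2.99 ± 0.036 with DMSO, 3.48 ± 1.04 with QC6352, 2.71 ± 0.024 with shCtrl, 2.45 ± 0.020 with shKDM4B-813 and 2.46 ± 0.18 with shKDM4B-814. Whether the authors sampled reads to a common number before calling peaks is not settled in the sources used here, so this value is not read as sequencing depth, which stays unknown. List lengths were made equal because they differed.

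Within each experiment every list was trimmed to the length of the shortest, keeping the strongest peaks by −log10 q, then fold, then position: 170390 peaks in LHCN, 105136 in the compound experiment and 93488 in the hairpin experiment. The trimmed peaks were merged into a union of regions, and a library was present in a region if a peak overlapped it by 1 bp or more. A region was gained if present in all treated and no control libraries, and lost in the reverse case. The counts were compared with the mixed splits of the same libraries (14 other splits for both hairpins), since 2 against 2 gives no p below 0.333. This asks only whether libraries agree more within groups than between them, whatever the reason. The calling rule was tested on simulated presence data with 500 seeded regions each way per comparison, on as many regions as the real sets. It recovered 100% of gained and 99.6% of lost regions for PAX3-FOXO1, 99.8% and 99.6% for QC6352, 99.4% and 99.0% for shKDM4B-813, and 99.8% and 99.2% for shKDM4B-814. The seeded patterns follow the rule itself, so this checks the code and not how real differences or false calls behave.

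Similarity was the Jaccard index of region presence, tested by exact permutation over all pairings of the libraries. The LHCN calls defined PAX3-FOXO1-gained, PAX3-FOXO1-lost and LHCN-shared regions, and 11845 regions open in at least 5 RH30 libraries and in no LHCN library were RH30-only regions. For the pooled test of KDM4 perturbation, labels were permuted within each experiment (90 label sets, smallest p 0.0111), with Benjamini-Hochberg adjustment over 6 values. The shares at equal strength were expected values over 20 bins of within-list percentile. Overlaps of called regions were set beside the product of list sizes over the number of regions. For the hairpins, which share controls, 20 simulated draws of unchanged groups were added. Intervals are 95% Wilson intervals over regions, which are not replicates.

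The rule for named regions was fixed before the data were examined: per comparison and direction, the 10 regions with the highest lower-of-2 within-list percentile, some of them printed. Windows of 1 Mb, the density classes, the region class comparison, the DMSO libraries as control for the hairpins and the single shCtrl library per hairpin were chosen after seeing the data. Coordinates are hg19 and count from 1. No annotation or sequence of that build was used here, so no region is assigned to a gene, and the planned gene lists, motifs, promoter shares and cell type markers were not run. Alternatives covered the lists as deposited, a limit of −log10 q of 10, the 50000 strongest peaks, strong against absent peaks, a coverage of 50% of the region, fixed windows on summits, replicate blocks and leaving out each library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.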

Results

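Chromatin accessibility was profiled by ATAC-seq, which marks open DNA by the insertion of sequencing adapters with the Tn5 transposase, in 14 libraries of human muscle-lineage cells. LHCN, an immortalised human myoblast line, carried an empty vector or expressed PAX3-FOXO1, the fusion transcription factor of alveolar rhabdomyosarcoma, for 72 h. RH30, an alveolar rhabdomyosarcoma line with its own PAX3-FOXO1 fusion, received 0.1% DMSO or 200 nM QC6352, an inhibitor of the KDM4 histone demethylases. In a separate RH30 experiment the cells were transduced for 72 h with a control hairpin (shCtrl) or with shKDM4B-813 or shKDM4B-814 against KDM4B, a member of that demethylase family. Each of the 7 groups held 2 libraries, so every SD below has n = 2. KDM4B levels were not measured by this assay, and the depth of the knockdown is therefore not known here.

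The 4 LHCN lists were long and even, with 174034 ± 1100 peaks (mean ± SD, n = 2) with vector and 172992 ± 3680 with PAX3-FOXO1. The RH30 lists held 117236 ± 17113 peaks with DMSO, 144086 ± 46405 with QC6352, 141161 ± 7402 with shCtrl, 139613 ± 1031 with shKDM4B-813 and 96574 ± 4364 with shKDM4B-814. The QC6352 spread came from lists of 111272 and 176899 peaks. The background pileup with any added constant, read from the step of the authors' fold values, ran from 2.33 in the second shKDM4B-814 library to 4.21 in the second QC6352 library. Because of these differences the lists were trimmed to equal length before any comparison.

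Replicates resembled each other more than they resembled other groups. The Jaccard index of regions with a peak, which is 1 for identical sets, was 0.855 between the vector libraries and 0.819 between the PAX3-FOXO1 libraries of LHCN, against 0.650 across those groups. Among the RH30 pairs it was 0.662 for shKDM4B-813, 0.654 for DMSO, 0.599 for shKDM4B-814, 0.550 for shCtrl and 0.547 for QC6352. Over the 10 RH30 libraries the index averaged 0.60 within groups and 0.487 between groups on the RH30 region set, and no other way of pairing the libraries gave a larger gap (exact permutation test, one-sided, p = 0.00106, the smallest it allows). For LHCN the values were 0.759 and 0.609 on the LHCN region set, where 3 pairings allow no p below 0.333. That set used lists of 170390 peaks, against 93488 for the single LHCN indices above, so the values differ. The control-hairpin libraries stood apart from the other RH30 controls. Their index with the DMSO libraries was 0.447, lower than that of shKDM4B-813 (0.530) or shKDM4B-814 (0.571) with the same DMSO libraries.

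**Figure D1:**
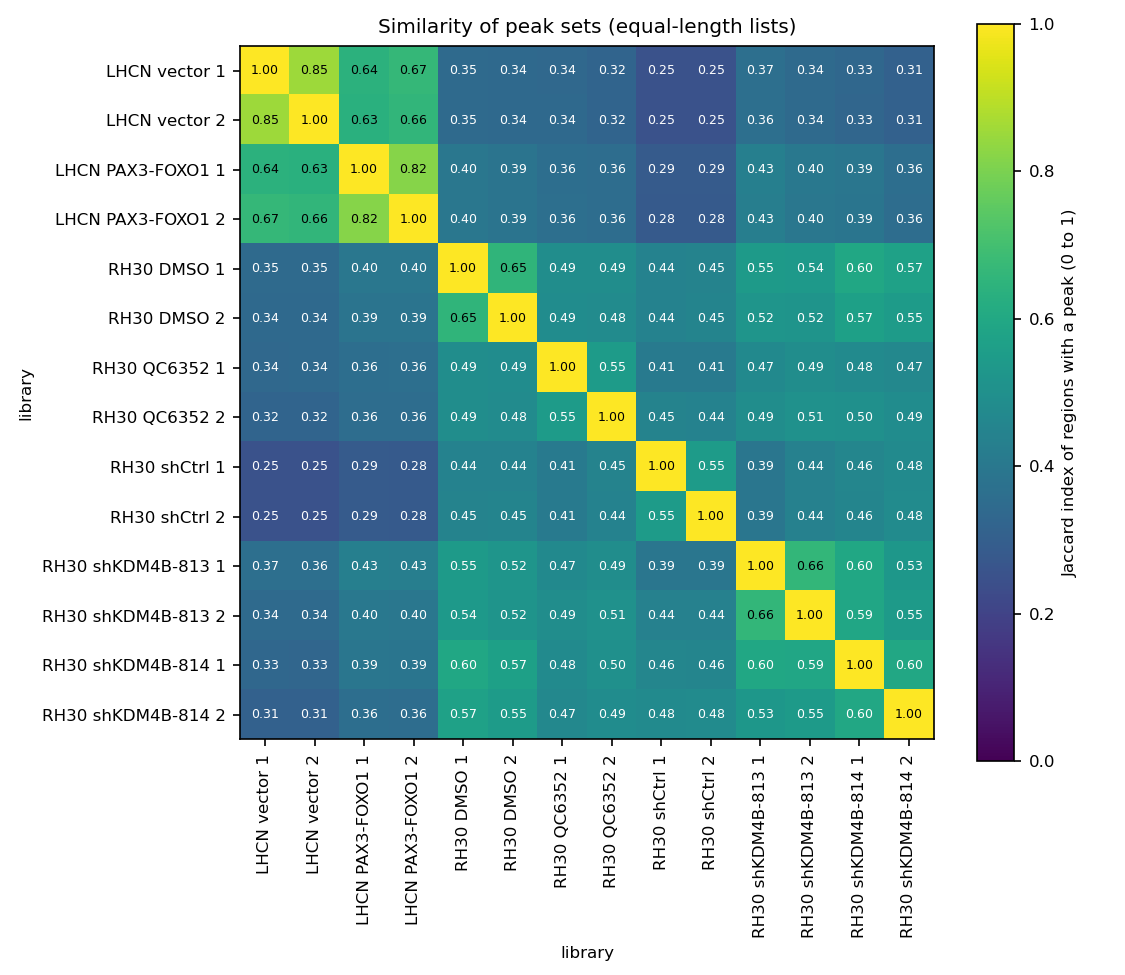
Jaccard index of regions with a peak for every pair of the 14 libraries, with lists trimmed to equal length; both axes list the libraries and colour gives the index from 0 to 1. Each library was closest to its replicate (0.547 to 0.855). Some RH30 pairs across groups, up to 0.597, exceeded the replicate pairs of QC6352 and shCtrl. LHCN and RH30 form separate blocks, and the shCtrl libraries sit at 0.447 to the DMSO libraries.

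Expression of PAX3-FOXO1 in LHCN myoblasts asks which sites the fusion opens or closes in a muscle precursor that lacks it. Similar numbers of regions were gained and lost in lists trimmed to equal length, and in the lists as deposited (18704 and 20461). Of 234279 regions, 19093 (8.15%) had a peak in both PAX3-FOXO1 libraries and in neither vector library, 19778 (8.44%) had the reverse, and 111758 were present in all 4 libraries. The 10 strongest gained regions were far stronger within their lists than the 10 strongest lost regions, at percentiles 97.0 to 99.0 against 81 to 87.8. The leading gained regions (hg19) were on chromosome 6 from 6320530 to 6321546, on chromosome 10 from 112935380 to 112936245, on chromosome 12 from 128563706 to 128564767 and on chromosome 8 from 90001807 to 90002614. Their peaks reached authors' fold values of 52.2 to 75.8, and the deposited vector lists held no weaker peak there. A gained pair lay on chromosome 10 from 37668720 to 37669507 and from 37766937 to 37767670; 1 vector library listed a weak peak in the former. The other leading gained regions were on chromosome 4 from 137839801 to 137840306, chromosome 5 from 116799476 to 116799913, chromosome 1 from 217075929 to 217077130 and chromosome 11 from 78973888 to 78974506.

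Among the lost regions of LHCN, the leading ones lay on chromosome 1 from 83616837 to 83617172, chromosome 10 from 93402428 to 93403191, chromosome 9 from 98918227 to 98919251 and chromosome 3 from 42820676 to 42821451. Their authors' fold values in the vector libraries were 30.0 to 40.8. A stricter rule separated the directions. When a strong peak was required in one group (among the 50000 strongest) and no peak at all in the deposited lists of the other, 808 regions were gained and 84 lost. Most called regions were weak, with a median within-list percentile of 24.3 for gained and 21.7 for lost regions, against 64.5 for regions present in all 4 libraries.

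The 1 Mb windows with the most gained regions of LHCN were picked by count, with no test of clustering. The window of chromosome 2 from 1000001 to 2000000 held 58 gained and 0 lost regions, and the one from 16000001 to 17000000 held 55 and 1. On chromosome 11 the window from 84000001 to 85000000 held 42 gained and 0 lost among only 65 regions, and that from 78000001 to 79000000 held 43 and 4. On chromosome 1 the window from 14000001 to 15000000 held 40 gained and 1 lost. The windows with the most lost regions were mostly on chromosome 7, led by 130000001 to 131000000 with 33 lost and 2 gained. Over the whole of chromosome 7, 11.4% of regions were lost and 4.87% gained. Losses also exceeded gains on chromosomes 17, 19, 21 and 22, at 8.96% to 10.8% against 3.84% to 5.81%. On most other numbered chromosomes gains exceeded losses.

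The real grouping gave 38871 called regions, against 3575 and 3853 for the mixed splits of the same 4 libraries. With 2 libraries per group no region has a p below 0.333, so the counts carry no per-region test. Dropping a library loosens the rule. Without the first or second PAX3-FOXO1 library 30393 or 36575 regions were gained, without the first or second vector library 31961 or 30965 were lost, and without the second PAX3-FOXO1 library 29717 were lost.

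Sites that opened with the fusion in myoblasts were more often open in RH30 than sites that closed. Of the PAX3-FOXO1-gained regions, 14.6% (95% Wilson interval 14.1 to 15.1) had a peak in all 4 RH30 control libraries. Of the PAX3-FOXO1-lost regions 1.52% did (1.36 to 1.70), an odds ratio of 11.1 between the sets. Regions present in all 4 LHCN libraries were open in RH30 most often, at 30.5% (30.3 to 30.8). These intervals cover counting error over regions, which are not replicates. When any RH30 control library sufficed, the shares were 35.9%, 9.99% and 56.2%. At the level of whole libraries, all 10 RH30 libraries were closer to the PAX3-FOXO1 libraries of LHCN (mean Jaccard index 0.286 to 0.428) than to the vector libraries (0.251 to 0.365). The gap was 0.0218 to 0.0630 and held for every pair of LHCN libraries, although 4 LHCN libraries allow no p below 0.333.

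QC6352 was compared with its DMSO vehicle in RH30 to see which accessible sites depend on KDM4 activity. In lists trimmed to equal length, which favours a balance, similar numbers of sites were gained and lost with the compound. Of 170777 regions, 11059 (6.48%) were gained, 12307 (7.21%) were lost and 48514 were present in all 4 libraries. The leading lost regions were on chromosome 17 from 18966746 to 18967017, chromosome 3 from 149888894 to 149889282, chromosome 7 from 44029576 to 44030213 and chromosome 2 from 26474754 to 26475161, with authors' fold values of 25.0 to 30.6 in the DMSO libraries and no peak listed with QC6352. A further pair of lost regions lay on chromosome 1 from 68169788 to 68170430 and on chromosome 10 from 99522457 to 99523330. The leading gained regions were on chromosome 12 from 60366551 to 60367899, where 1 DMSO library listed a weak peak, chromosome 3 from 86465484 to 86465891, chromosome 18 from 30502805 to 30503455 and chromosome 1 from 78804978 to 78806578, which also had a weak peak in 1 DMSO library. Their authors' fold values were 14.5 to 19.3.

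The windows with many QC6352 losses named here were picked by count, with no test of clustering. On chromosome 11 the window from 78000001 to 79000000 had 88 lost and 4 gained among 436 regions, and the next, to 80000000, had 66 and 2 among 313. The first of these was also among the windows with the most PAX3-FOXO1-gained regions in LHCN. On chromosome 6, 60 regions were lost and 10 gained among 509 between 72000001 and 73000000. The window with the most QC6352 gains, on chromosome 9 from 136000001 to 137000000, held 108 gained and 2 lost among 401 regions. That on chromosome 17 from 17000001 to 18000000 held 101 and 3 among 411. A ranking by count favours windows with many regions. In the first chromosome 11 window and those on chromosomes 6, 9 and 17, RH30 libraries averaged 4.55 to 8.18 times the LHCN peak number.

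The real grouping gave 23366 called regions, against 4265 and 4808 for the mixed splits. On the region set of all 10 RH30 libraries QC6352 differed from DMSO in 19799 regions. There the shCtrl libraries, controls of the other experiment, differed from DMSO in 25111. The count alone therefore does not show an effect of the compound. The balance of directions changed with the setting, and the reason was not tested. In the lists as deposited, which averaged 144086 peaks with QC6352 and 117236 with DMSO, 16056 regions were gained and 10627 lost. With only peaks of −log10 q of 10 or more, 3778 were gained and 8345 lost. Those lists held 45625 and 61971 peaks with QC6352 and 59497 and 58637 with DMSO. Without the first or second QC6352 library 33158 or 28446 regions were gained and, without the second, 19477 were lost; without the first or second DMSO library 28724 or 27390 were lost.

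**Figure D2:**
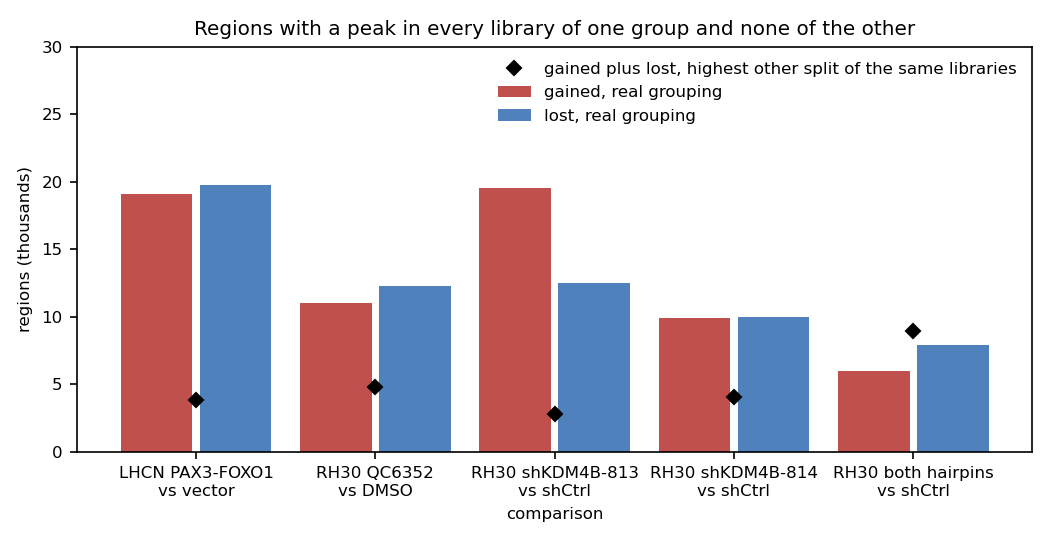
Regions gained (red bars) and lost (blue bars) for each comparison on the horizontal axis; diamonds give the gained plus lost count of the highest-scoring other split of the same libraries. The real groupings gave 38871, 23366, 32064 and 19872 regions against 3853, 4808, 2780 and 4076, and 13886 against 8956 for both hairpins together.

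Fewer of the sites gained with PAX3-FOXO1 in myoblasts had a peak with QC6352 than with DMSO. With DMSO 26.2% ± 0.71 of the PAX3-FOXO1-gained regions had a peak, and with QC6352 19.8% ± 2.34 did. For the PAX3-FOXO1-lost regions the shares were 4.78% ± 0.58 and 7.14% ± 0.52, and for regions shared by all LHCN libraries 47.5% ± 0.020 and 45.4% ± 0.11. For these shares all RH30 lists were trimmed to 93488 peaks, the shortest RH30 list. In these lists the QC6352 libraries of each class did not overlap the DMSO libraries, but 2 against 2 allows no p below 0.333 (exact permutation test, two-sided, p = 0.333). The region calls used the compound experiment's lists of 105136 peaks. Region by region, 23.8% of the PAX3-FOXO1-gained regions present with DMSO were lost with QC6352 (Wilson interval 22.5 to 25.0), 1.48 times the share for DMSO peaks of equal strength (interval 1.40 to 1.56). The LHCN-shared regions lost 8.74%, 0.703 times the share at equal strength. Regions with no peak in any LHCN library lost 39.4%, 1.35 times. Among regions present with QC6352, 28.6% of the PAX3-FOXO1-lost regions were gains, 1.48 times the share at equal strength, and 10.8% of the PAX3-FOXO1-gained regions were, 0.638 times. Neither ratio was particular to these classes. It was 0.617 for LHCN-shared regions (7.20%) and 1.49 for regions with no peak in any LHCN library (45.7%). In the lists as deposited the second QC6352 library, at 28.8%, lay between the DMSO libraries (28.2% and 29.7%) for PAX3-FOXO1-gained regions. There the LHCN-shared regions overlapped as well, at 48.8% and 51.1% with DMSO and 47.1% and 53.1% with QC6352.

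**Figure D3:**
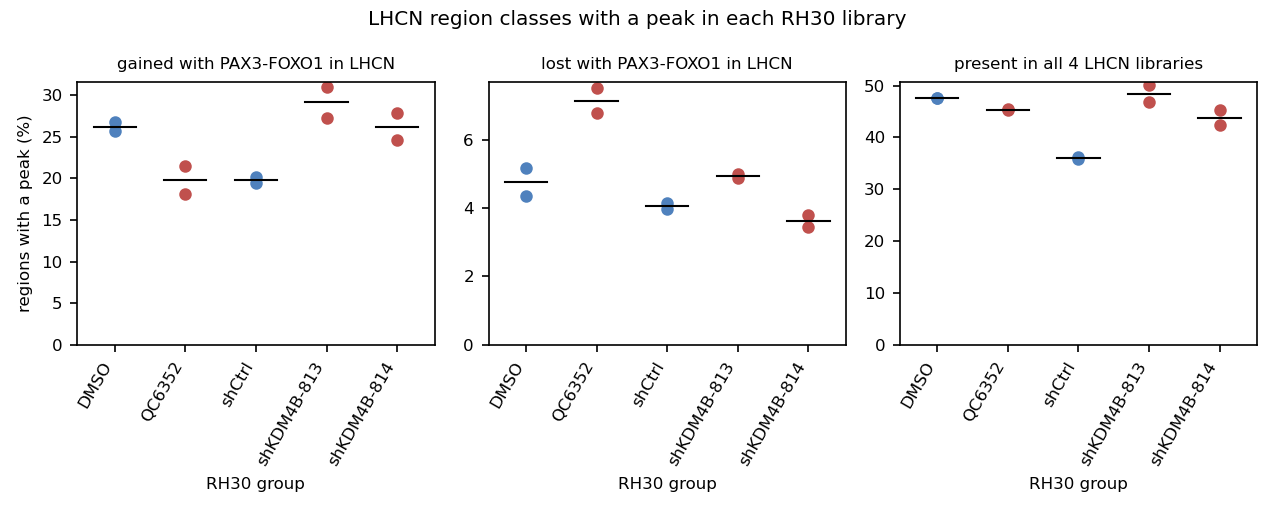
Share of LHCN region classes with a peak (vertical axis, %) in each RH30 library (points) with the group mean (line); blue marks DMSO and shCtrl and red marks QC6352 and the KDM4B hairpins. PAX3-FOXO1-gained regions stood at 26.2% with DMSO, 19.8% with QC6352, 19.8% with shCtrl, 29.1% with shKDM4B-813 and 26.2% with shKDM4B-814.

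The KDM4B hairpins were compared with the control hairpin to ask which sites depend on KDM4B itself. Both hairpins gained sites that shCtrl lacked and lost sites that shCtrl had, over 174406 regions. shKDM4B-813 gained 19528 (11.2%) and lost 12536 (7.19%), with 40395 regions present in all 4 libraries. shKDM4B-814 gained 9898 (5.68%) and lost 9974 (5.72%), with 43159 present in all 4. The leading regions gained with shKDM4B-813 were on chromosome 5 from 28543009 to 28543542, chromosome 12 from 16736563 to 16737826, chromosome 3 from 36207970 to 36208331 and chromosome 1 from 83616844 to 83617172. Their authors' fold values were 27.5 to 43.8, and 1 shCtrl library listed a weak peak in the chromosome 12 region. The chromosome 1 region overlapped the leading region lost with PAX3-FOXO1 in LHCN. The leading lost regions of shKDM4B-813 were on chromosome 3 from 48464716 to 48466195, chromosome 22 from 24034930 to 24035727 and chromosome 5 from 138001484 to 138001868. All 10 leading lost regions still had a weaker peak in a deposited shKDM4B-813 list. With the strict rule on strong against absent peaks, shKDM4B-813 gained 4603 regions and lost 382.

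For shKDM4B-814 the leading gained regions were on chromosome 3 from 94110219 to 94110653, chromosome 2 from 82062431 to 82063097, chromosome 5 from 31232398 to 31232699 and chromosome 11 from 23333597 to 23333865, with authors' fold values of 13.3 to 20.5. The leading lost regions included those on chromosome 9 from 130526041 to 130526827 and from 137604531 to 137605245, and on chromosome 1 from 1095506 to 1096884, with fold values of 9.54 to 12.5 in the shCtrl libraries. Both hairpins together gained 5981 regions and lost 7905. The chromosome 3 and chromosome 2 regions led the shared gains, and the first chromosome 9 region led the shared losses, although 2 hairpin libraries still listed a weaker peak there. Of the 10 leading shared losses 9 had such a weaker peak in a deposited hairpin list, and of the 10 leading shared gains 1 had it in a shCtrl list. The window with the most shared gains, on chromosome 6 from 72000001 to 73000000, held 31 gained and 0 lost among 514 regions. The windows with the most shared losses, on chromosome 19 from 1000001 to 2000000 and on chromosome 1 from 2000001 to 3000000, held 102 lost among 418 regions and 89 among 441, with 0 gained. No test of clustering was run.

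The real groupings gave 32064 regions for shKDM4B-813 and 19872 for shKDM4B-814, against at most 2780 and 4076 for the mixed splits. For both hairpins the total was 13886, above the highest of the 14 other splits into 4 and 2 libraries (8956); with only peaks of −log10 q of 10 or more it was 6625, below the highest other split (8312). The control libraries weighed on these counts. The shCtrl libraries differed from the DMSO libraries in 25111 regions (10505 gained and 14606 lost), more than shKDM4B-813 did (20134) or shKDM4B-814 did (11432). Set against DMSO, both hairpins shared 1890 gained and 4322 lost regions. In the lists as deposited shKDM4B-813 gained 25926 and lost 18920, shKDM4B-814 gained 7688 and lost 26775, and both gained 5487 and lost 15880. With only peaks of −log10 q of 10 or more, the counts were 17888 and 2951 for shKDM4B-813 and 5993 and 3538 for shKDM4B-814.

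Single libraries moved several hairpin counts. Without the second shKDM4B-813 library 35204 regions were gained with shKDM4B-813, and without the first or second shCtrl library 30939 or 29726 were lost. For shKDM4B-814, 22809 or 25741 were gained without its first or second library, and 27041 or 26027 were lost without the first or second shCtrl library. For both hairpins 10507 were gained without the second shKDM4B-814 library and 9418 or 9407 without the first or second shCtrl library, where 23354 or 22553 were lost.

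The sites called with the hairpins overlapped. Of the regions gained with shKDM4B-814, 60.4% were also gained with shKDM4B-813, and of those lost, 79.3% were also lost. Independent lists of these sizes would share 1108 gained and 717 lost regions. The observed counts were 5.40 and 11 times those. Groups with no difference, simulated with shared controls, shared 910 gained and 1853 lost regions, 7.43 and 15.1 times independent lists. Their lists were shorter, with 4637 and 4625 regions on average, and the ratio depends on list length, so these ratios are not comparable. A split of the controls left 1 shCtrl library per hairpin. With the same library for both hairpins the overlap was 4.53 to 4.63 times that of independent lists for gains and 4.87 to 5.08 for losses, and with different libraries 2.89 to 2.93 and 1.71 to 1.72. A region shared with different libraries must meet the rule against both shCtrl libraries, so the shared counts stayed at 5981 and 7905. With the same library the rule is looser, so its higher ratio followed from the rule. The split therefore does not show how much of the excess came from the shared controls. Both hairpins were measured against a single control group.

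The same region classes were measured with the hairpins. PAX3-FOXO1-gained regions had a peak in 19.8% ± 0.53 of cases with shCtrl, 29.1% ± 2.64 with shKDM4B-813 and 26.2% ± 2.33 with shKDM4B-814. Regions shared by all LHCN libraries stood at 36.1% ± 0.38, 48.4% ± 2.35 and 43.8% ± 1.99. Hairpin libraries lay above the shCtrl libraries in both classes, with p = 0.0667 (exact permutation test, two-sided, 15 label sets), the smallest that 6 libraries allow. The shCtrl libraries were also below the DMSO libraries in both classes. Among regions present with shCtrl, 8.19% of the PAX3-FOXO1-gained regions were lost with shKDM4B-813 and 4.34% with shKDM4B-814, 0.483 and 0.328 times the share at equal strength. LHCN-shared regions lost 4.15% and 2.81%, 0.301 and 0.265 times. Losses fell mainly on regions with no peak in any LHCN library, of which 56.5% and 47.0% were lost.

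Calls with QC6352 and with the hairpins shared more gains than chance gives but, over all regions, no more losses. Some opposite calls were as far above chance as the shared gains. Chance was the product of the list sizes over the number of regions, which treats all regions as equally likely to be called. Values above it therefore do not by themselves show shared or opposed effects. Over 203312 regions of the RH30 set, QC6352 and shKDM4B-813 shared 1840 gained regions where chance gives 840, and 581 lost regions where chance gives 592. With shKDM4B-814 they were 532 where chance gives 423, and 195 where chance gives 465. Some opposite calls were also above chance: 1073 regions gained with QC6352 were lost with shKDM4B-813 (chance 488) and 867 with shKDM4B-814 (chance 383), while 1083 regions lost with QC6352 were gained with shKDM4B-814 (chance 514). The fourth pair, lost with QC6352 and gained with shKDM4B-813, held 1047 where chance gives 1020. When chance was computed within 1 Mb windows, shared gains were 2.15 times chance with shKDM4B-813 and 1.34 times with shKDM4B-814. QC6352 gains lost with these hairpins were 1.75 and 1.70 times, and QC6352 losses gained with them 0.905 and 1.71 times. Shared losses were then 1.74 times chance with shKDM4B-813. With shKDM4B-814 shared losses were 0.840 times, nearer to chance than the 0.419 times over all regions. For shKDM4B-813 shared losses were 1.38 times chance with the 50000 strongest peaks and 0.632 times in the lists as deposited. With the 50000 strongest peaks, regions gained with QC6352 and lost with shKDM4B-813 fell below chance, at 0.889 times.

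Pooled over both experiments, no summary value separated the 6 KDM4-perturbed libraries from the 4 controls. Perturbed minus control was 0.69 percentage points for PAX3-FOXO1-gained regions (exact permutation test within experiments, two-sided, p = 0.811), 1.29 for PAX3-FOXO1-lost regions (p = 0.133) and 3.95 for LHCN-shared regions (p = 0.133). By the same exact permutation test it was −0.0148 for regions open in RH30 only (p = 1) and 1891 for peak number (p = 0.922). For the ratio of the PAX3-FOXO1-gained to the LHCN-shared share it was −0.0333 (exact permutation p = 0.456). Adjusted over the family of 6 by Benjamini-Hochberg, the p-values were 0.40 to 1. The experiments went opposite ways for PAX3-FOXO1-gained regions, at −6.43 with QC6352 and 7.82 with the hairpins, and for LHCN-shared regions, at −2.17 and 10.1.

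Called regions differed in where they lay along the chromosomes. With 1 Mb windows ranked into 10 classes by the number of LHCN vector peaks, 11.4% of the regions in the densest class were lost with shKDM4B-813 and 2.08% in the sparsest; for shKDM4B-814 the shares were 9.74% and 0.92%. Gains ran the other way, at 5.43% and 20.4% for shKDM4B-813 and 2.74% and 9.60% for shKDM4B-814. QC6352 showed the opposite slopes, with 8.14% gained in the densest class and 4.71% in the sparsest, and 4.90% and 11.4% lost. The shCtrl libraries themselves had 25.5% and 25.5% of their peaks in the densest class, above the DMSO libraries at 19.5% and 20.4%. The QC6352 libraries were also above DMSO, at 24.3% and 22.3%. The shKDM4B-813 libraries stood at 17.3% and 19.5% and the shKDM4B-814 libraries at 18.8% and 19.9%. Against DMSO, gains with shKDM4B-813 still fell with density, from 13.3% in the sparsest to 2.38% in the densest class, and with shKDM4B-814 from 4.32% to 1.32%.

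**Figure D4:**
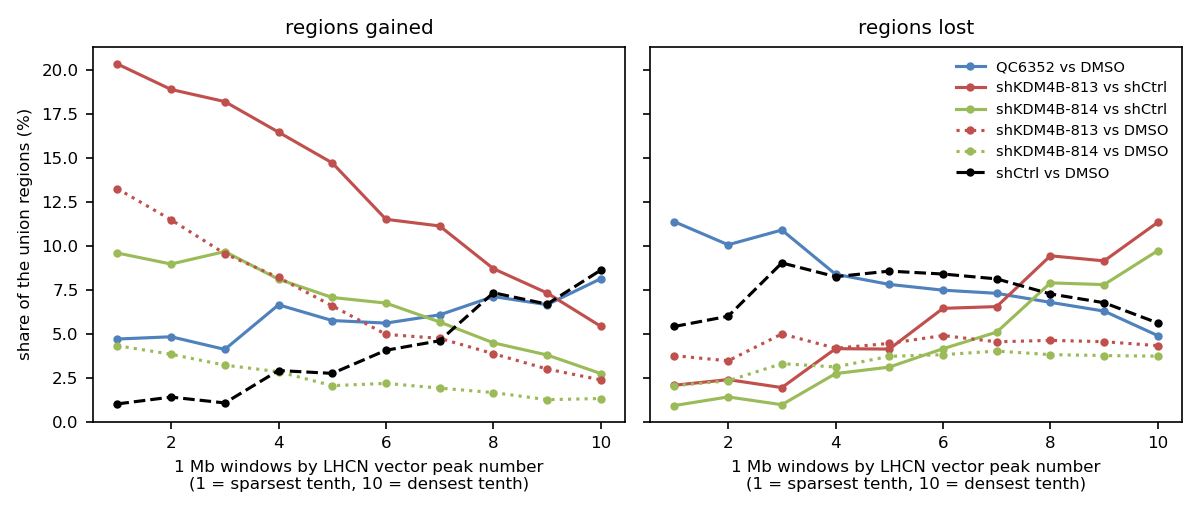
Share of regions gained (left) or lost (right) on the vertical axis (%) by class of 1 Mb windows on the horizontal axis, 10 classes ranked by the number of LHCN vector peaks from sparsest to densest; each line is a comparison between RH30 groups. Hairpin losses against shCtrl rose with density (2.08% to 11.4% for shKDM4B-813), as did regions present with shCtrl and absent with DMSO (1.01% to 8.63%).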

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

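The tests of explanations in this part were all chosen after the results were seen. In the trimmed lists several region classes moved one way in every QC6352 library and the opposite way in every library of a hairpin, each against its own controls. These differences were not tested. For PAX3-FOXO1-gained regions with a peak, QC6352 stood at −6.43 percentage points against DMSO, shKDM4B-813 at 9.28 and shKDM4B-814 at 6.36 against shCtrl. The hairpin values depend on a low shCtrl level, 19.8% against 26.2% with DMSO. With shKDM4B-813 the share was 29.1%, and with shKDM4B-814 26.2%, the level with DMSO. In the lists as deposited the shKDM4B-814 libraries stood at 28.6% and 24.6% and the shCtrl libraries at 22.7% and 24.0%. For LHCN-shared regions the values were −2.17, 12.4 and 7.79. In the lists as deposited the QC6352 libraries no longer separated from DMSO, with DMSO at 48.8% and 51.1% and QC6352 at 47.1% and 53.1%. The hairpin libraries still lay above shCtrl there. The shCtrl libraries stood at 39.4% and 40.5%, shKDM4B-813 at 58.2% and 52.4% and shKDM4B-814 at 45.9% and 42.4%. For PAX3-FOXO1-lost regions QC6352 stood at 2.36, shKDM4B-813 at 0.87 and shKDM4B-814 at −0.45, so shKDM4B-814 went against both of the others. The ratio of the PAX3-FOXO1-gained to the LHCN-shared share moved by −0.115 with QC6352, 0.0505 with shKDM4B-813 and 0.0469 with shKDM4B-814. In the lists as deposited the second shKDM4B-814 library, at 0.579, lay between the shCtrl libraries (0.576 and 0.591).

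The loss of PAX3-FOXO1-gained regions with QC6352 was weighed against technical explanations. If weak peaks alone were lost, the observed loss would equal that of peaks of equal strength, but it was 1.48 times as high with a lower bound of 1.402, and in the mixed splits of the same 4 libraries the ratio was 0.451 to 1.02. At equal strength and equal window density it was 1.422, which argues against the density shift as the whole cause. List length stays open: in the lists as deposited the mean difference was −4.669 percentage points, but the second QC6352 library fell between the DMSO libraries, although the ratio at equal strength was then 1.52. It was 1.21 to 1.41 when any of the 4 libraries was left out. An effect of the compound itself, which the design names, also stays open and was not tested separately. With the KDM4B hairpins the ratios against shCtrl were 0.483 and 0.328, and LHCN-shared regions stood lower still, at 0.301 and 0.265. These ratios rest on the shCtrl libraries, so they do not show whether the hairpins shared the loss seen with QC6352.

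The slope of the hairpin calls with the density of accessible sites was the next pattern. Regions present with shCtrl and absent with DMSO were 8.527 times as frequent in the densest as in the sparsest of 10 window classes, a slope that contains no KDM4B hairpin library, so the shCtrl libraries may account for much of the losses in dense windows. Loss against DMSO was 1.152 times as frequent in the densest class for shKDM4B-813 and 1.822 times for shKDM4B-814. An effect of the knockdown in dense windows cannot be told apart from differences between the experiments, since DMSO is the control of another experiment.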

How the results depend on the processing

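The DMSO control for the hairpins, the single shCtrl library per hairpin, the chance within 1 Mb windows and the left-out LHCN libraries were chosen after seeing the data. For RH30 the gap in similarity within and between groups was 0.106 in the lists as deposited and 0.163 with correlations, against 0.114; its p stayed at the smallest possible, and for LHCN no p under 0.05 was possible. Window or coverage rules moved no count of called regions by over 1.5 times. Except where stated, the cause was not tested. Counts are given as gained and lost. With the 50000 strongest peaks they were 7285 and 6574 for PAX3-FOXO1, 4926 and 6413 for QC6352, 9236 and 6208 for shKDM4B-813, 5498 and 4703 for shKDM4B-814, and 3066 and 3995 for both, since fewer peaks entered. Strong against absent peaks gave 808 and 84, 1411 and 1492, 4603 and 382, 1736 and 1001, and 887 and 179. A −log10 q of 10 or more gave 3778 gained with QC6352, 2951 lost with shKDM4B-813, 5993 and 3538 with shKDM4B-814, and 2265 lost with both. The lists as deposited gave 18920, 26775 and 15880 lost with shKDM4B-813, shKDM4B-814 and both. With DMSO as control, shKDM4B-813 gained 11136, shKDM4B-814 4237, and both 1890, with 4322 lost.

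Leaving out a library asks for fewer libraries and so calls more regions. Gained and lost ranged from 23455 to 36575 and 24672 to 31961 for PAX3-FOXO1, 14098 to 33158 and 17625 to 28724 for QC6352, 24330 to 35204 and 14473 to 30939 for shKDM4B-813, 14584 to 25741 and 12783 to 27041 for shKDM4B-814, and 6553 to 10507 and 8152 to 23354 for both. Shares open in RH30 ranged over 10.1% to 14.7% of gained, 1.53% to 2.26% of lost and 28.3% to 29.9% of shared regions; any control library gave 35.9%, 9.99% and 56.2%, and the lists as deposited 15.4%, 1.94% and 32.2%.

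Pooled differences had no p under 0.05 in the main setting, the lists as deposited or with a library left out; either experiment alone cannot reach it. Those near 0 changed sign. Peak number was −23068 in the hairpin experiment alone and −14516 to 18298 with a library left out (−4160 without the first DMSO, −726 without the first shCtrl, −1817 and −1574 without the first and second shKDM4B-813 library). PAX3-FOXO1-gained regions were −6.43 in the compound experiment alone and −0.135 to 1.52 with a library left out; LHCN-shared regions were −2.17 in the compound experiment. RH30-only regions were 2.38 in the lists as deposited, 4.05 in the hairpin experiment and −3.01 to 2.98 with a library left out (0.167 without the first DMSO, 0.329 without the second shCtrl, 1.61 without the first shKDM4B-813 library). The ratio of shares was 0.0486 in the hairpin experiment.

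Overlap over chance changed too. QC6352 losses with shKDM4B-813 gains were 0.905 with chance within 1 Mb windows and 0.652 with the 50000 strongest peaks. Shared losses with shKDM4B-813 were 1.74, 0.632 in the lists as deposited and 1.38 with the 50000 strongest; with shKDM4B-814 they were 0.840 within windows. With the 50000 strongest, QC6352 gains over shKDM4B-813 losses were 0.889, over shKDM4B-814 gains 1.90 and over shKDM4B-814 losses 1.24. With a different shCtrl library per hairpin, and so longer lists, the overlap of the hairpins was 2.93 and 2.89 against 5.40 for gains and 1.715 and 1.712 against 11 for losses.

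Replicate numbers did not pair the libraries, since same-numbered deviations correlated at −0.0124 to 0.00618. Applied as a block within same-numbered pairs, the rule gave 19093 and 19778 regions for PAX3-FOXO1 and 11059 and 12307 for QC6352; the hairpin counts and pooled differences also equalled the main values, all by construction. The gene list, motif and promoter alternatives were not run, for lack of an hg19 annotation here. An unlisted peak can lie just under the authors' limit.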

Other observations

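The tests here were chosen after the results were seen. RH30 held very wide peaks on chromosome 12 between 57000001 and 59000000 (hg19). Every RH30 library had 33 to 56 peaks of 5 kb or more there, LHCN libraries had 0, and peaks covered 1248 to 1514 kb of these 2 Mb in RH30 against 95.7 to 104 kb in LHCN. The treatments cannot be the source, since the DMSO and shCtrl libraries held at least 43 such peaks each. Extra copies of this segment in RH30 may give a raised background that the caller reads as wide peaks. The lowest RH30 count of 33 against 0 in LHCN lends this no support over any other stable difference between the lines, and copy number was not measured here.

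RH30 libraries were also dense in other blocks. In 30 windows of 1 Mb the mean RH30 peak number was at least 100 and at least 4 times that of LHCN. They included 6 on chromosome 6 between 68000001 and 75000000, 6 on chromosome 9 between 133000001 and 141000000 and 6 on chromosome 11 between 69000001 and 79000000. In the chromosome 6 window from 72000001 to 73000000 the DMSO libraries held 359 and 305 peaks, QC6352 159 and 232, shCtrl 167 and 157, shKDM4B-813 253 and 269 and shKDM4B-814 395 and 362, and LHCN libraries 30 to 36. This window also carried QC6352 losses and shared hairpin gains.

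In LHCN, 26.5% of the regions in the sparsest of 10 window classes were gained with PAX3-FOXO1 and 4.37% in the densest, while losses rose from 4.39% to 9.50%. The classes were ranked on vector peaks, so part of the gain slope follows from the ranking itself. Lost regions hold vector peaks, which count towards that ranking, so it also favours the rise in losses.

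In RH30, 442 regions had a peak in all 6 KDM4-perturbed libraries and in none of the 4 controls, and 114 had the reverse. Of the 90 label sets within the experiments, 3 gave 556 or more, but sets that split a replicate group gave at most 425 and all 3 were among the 6 sets that keep the groups whole. This share therefore does not exclude chance, and 6 whole-group sets allow no share under 0.05. The real count was 556 and the highest other 1078, from treating the QC6352 and shCtrl libraries as the controls. Such a split points to a structure of the samples, the nature of which was not tested. The QC6352 and shCtrl libraries also held 22.3% to 25.5% of their peaks in the densest window class, more than any other RH30 library.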
